A study of Mus musculus with 18 samples.

How the data were processed

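RNA was sequenced from mouse CD4 T cells in 18 libraries that form 6 groups of 3. Each library was read as single-end reads of 50 bases on an Illumina HiSeq instrument, from total RNA, with a Nugen/Nextera XT preparation, per the labels' protocols. The values used were a table of raw read counts per Ensembl gene as deposited by the authors, with 1 column per library and no normalization. Per the submitters' processing notes, the reads were aligned with STAR 2.7.2 to GRCm38 and DESeq2 was used. The counting step, the annotation release, the strand setting, any filter and the version of DESeq2 are not given in the sources used here. The whole numbers in every column and the column totals were checked against that unit. The reads themselves were not analysed here.

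The table held 55536 gene identifiers, all of which matched GENCODE mouse release M21 (Ensembl 96, GRCm38), and 25739 of them had a count of 0 in all libraries. There were 0 identifiers without a match and 0 columns without a sample, and 233 identifiers shared their symbol with another. Coordinates are 1-based on GRCm38. Column totals ran from 19708218 to 36218772 counts. A gene absent from a group has a floor of 3 counts summed over the group's libraries, and a fold against such a group is given as a bound against that floor; floors cover counting error only, since PCR copies are not independent molecules.

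Groups were taken from the sample titles. They were peripheral OTII, W131AOTII, Cbl-b-/- OTII and Cbl-b-/-W131AOTII cells and thymic OTII and W131AOTII cells. Per the labels' protocols, the cells came from 3 OTII, 12 W131AOTII, 3 Cbl-b-/- and 6 Cbl-b-/-W131AOTII mice, with 4 mice per group named for W131AOTII and 2 for Cbl-b-/-W131AOTII. How mice map to libraries, and whether thymus and periphery came from the same animals, are not given in the sources used here, so the p-values measure the spread between these libraries.

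All libraries entered 1 edgeR 4.0.16 fit in R 4.3.3, with 1 mean per group and 12 residual degrees of freedom. Genes were kept by filterByExpr on the groups, which left 15204. Scaling used TMM factors, the quasi-likelihood fit was robust, and contrasts were tested with the quasi-likelihood F test, Benjamini-Hochberg adjusted over the genes of a comparison, at a threshold of 0.05. CPM values are edgeR's, on TMM-scaled library sizes, and log2 CPM for principal components used a prior count of 2. The standard error (SE) beside a log2 fold change comes from the same fit. The 9 comparisons were 5 between peripheral groups, 1 between thymic groups, the OTII periphery against the OTII thymus, and 2 differences between effects, the interaction of W131A with Cbl-b-/- in the periphery and the W131A effect in the periphery against that in the thymus. Fold changes of comparisons that share no library were also correlated across genes, which are not independent replicates, so no p is given.

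There were 35 gene lists. They covered anergy-associated genes, T cell receptor activity reporters, inhibitory receptors, negative regulators of T cell receptor signalling, proximal T cell receptor signalling, the calcium and NFAT pathway, the PI3K, AKT and mTOR pathway, the NF-kB pathway and targets, regulatory T cell markers, naive T cell and quiescence genes, effector and memory T helper genes, follicular helper T cell genes, the type I interferon response, cell cycle genes, immature thymocyte genes, strong-signal thymic selection genes, apoptosis and survival genes, cytokines and cytokine receptors, glycolysis, cholesterol synthesis, tissue handling and heat shock genes and the unfolded protein response. Lists of other cells and of controls were B cell markers, CD8 T cell markers, NK and innate-like T cell markers, myeloid and dendritic cell markers, erythroid and platelet markers, thymic stroma and epithelium markers, sex-linked genes, housekeeping genes, mitochondrially encoded genes, ribosomal protein genes, T cell receptor variable segments, immunoglobulin segments and replication-dependent histone genes. Lists share members, such as Egr2, Nr4a1 and Pdcd1. Each list was tested in each comparison with limma 3.58.1 camera on voom values at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison (315 tests in all), and again with a correlation estimated from the residuals and with fry. Member counts come from the edgeR test adjusted over all genes, and a second count is "adjusted over the list alone".

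Genes were named by a rule. It took Cblb and Zap70, 20 focus genes, up to 10 genes in each direction with the smallest adjusted p among those that changed at least 2-fold and whose libraries did not overlap between the groups (no overlap was asked of the differences between effects), and up to 4 members of each list past the threshold, with the 2 most abundant for the other-cell lists. Segments of antigen receptors, predicted genes and pseudogenes were only counted. Groups, comparisons, tests, lists, the naming rule and most alternatives were fixed before the data were examined.

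Alternatives fixed then were DESeq2 size factors (RLE), library size alone, no low-count filter, CPM above 1 in at least 3 libraries, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, only the libraries of the groups compared, the replicate number as a block, a gene set without receptor segments, sex-linked, mitochondrial and ribosomal protein genes, and each library left out in turn. Those left-out fits kept the 15204 genes. Alternatives chosen after the data were seen were offsets per library for GC content and transcript length (natural splines with 5 degrees of freedom, known for 15198 genes) and a fit without 3 libraries that stood apart. Other splits of the libraries were enumerated in full, 10 for each pair of groups and 200 for each difference between effects.

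The steps were tested on simulated data built on the real libraries' means and spread. In simulated peripheral W131AOTII libraries against OTII, the edgeR fit recovered 16.4% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 95.5% of those changed 4-fold, with 5 false calls. In simulated data for the interaction, 4.48%, 22.4% and 81.8% were recovered at the same folds.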

Results

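Gene expression was measured by RNA sequencing in CD4 T cells of C57BL/6 mice that carried OT-II, a transgenic T cell receptor specific for an ovalbumin peptide. The W131AOTII mice additionally carried W131A, a substitution in the kinase ZAP-70 that weakens its autoinhibited conformation, and the series describes them as a genetically encoded model of T cell anergy. The Cbl-b-/- mice lacked Cbl-b, an E3 ubiquitin ligase that restrains T cell receptor signalling. The stated purpose was to find pathways under Cbl-b control that restore responsiveness in anergy. Peripheral cells came from spleen and lymph nodes and were sorted as naive (low CD44, CD62L positive), CD25-negative and Va2-positive, and thymic cells were sorted as CD25-negative, Va2-positive CD4 single-positive thymocytes. There were 4 peripheral groups and 2 thymic groups, each of 3 libraries. Total counts of replicates 1 to 3 were 29851179, 30543980 and 28766735 in peripheral OTII, 36218772, 31916308 and 34229216 in W131AOTII, 19708218, 23850362 and 28538215 in Cbl-b-/- OTII and 31666268, 25634489 and 27156087 in Cbl-b-/-W131AOTII libraries. The thymic totals were 20001233, 31034603 and 22610022 in OTII and 26682250, 32262064 and 25509435 in W131AOTII libraries.

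Cblb (ENSMUSG00000022637, chromosome 16, 52031225 to 52208048) was measured at 129 ± 10.7 CPM (counts scaled by library size and TMM factor; SD, n = 3) in peripheral OTII, 159 ± 15.9 in W131AOTII, 69.5 ± 19.8 in Cbl-b-/- OTII and 93.6 ± 15.1 in Cbl-b-/-W131AOTII cells. In the thymus it was 90.8 ± 10.6 CPM in OTII and 126 ± 14.3 in W131AOTII cells. Cblb fell by 0.89 on the log2 scale (SE 0.17, edgeR quasi-likelihood adjusted p = 0.006) in Cbl-b-/- OTII against OTII cells and fell by 0.76 (SE 0.17, adjusted p = 0.014) in Cbl-b-/-W131AOTII against W131AOTII cells. Without Cbl-b-/-W131AOTII replicate 2 the latter adjusted p was 0.0525. Counts over the whole gene were lower but present in the Cbl-b-/- libraries, and the deleted exon is not given in the sources used here. Zap70 (ENSMUSG00000026117, chromosome 1, 36761798 to 36782818) was measured at 314 ± 39.6 CPM in OTII, 333 ± 30.9 in W131AOTII, 265 ± 61.9 in Cbl-b-/- OTII, 207 ± 21.6 in Cbl-b-/-W131AOTII, 369 ± 60.6 in thymic OTII and 348 ± 121 in thymic W131AOTII cells.

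**Figure D1:**
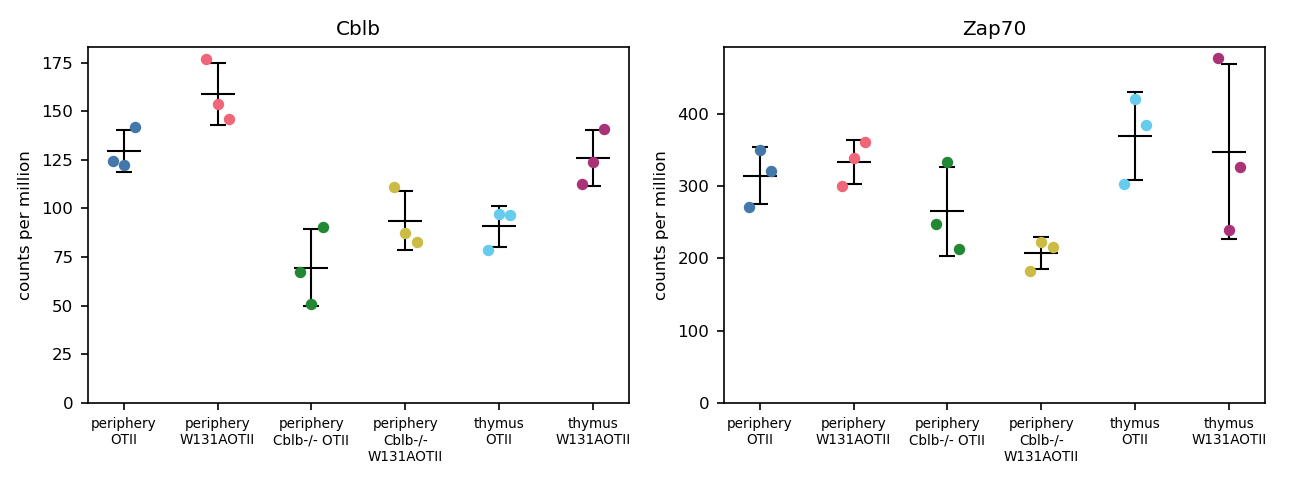
Cblb and Zap70 in CPM (linear axis from 0) in the 6 groups; points are libraries, horizontal lines are means and error bars are the SD (n = 3). Cblb means were 69.5 and 93.6 CPM in the peripheral Cbl-b-/- groups against 129 and 159 CPM in the other peripheral groups.

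Across the 500 most variable genes, component 1 held 69.8% of the variance and separated thymic from peripheral libraries, and component 2 held 7.82%. W131AOTII replicate 2 stood apart from every other library on component 2, at 38.7. That library carried more B cell and myeloid transcripts, with Cd79a, a chain of the B cell receptor, at 154 CPM against 28.4 and 17.4 in the other W131AOTII libraries, Igkc at 486 CPM and Lyz2, a myeloid lysozyme, at 61.8 CPM. Cd74, the class II invariant chain, was at 1969 CPM there against 345 and 280 CPM. Cbl-b-/- OTII replicate 2 had a ribosomal protein share of 1.85%, the highest of the 18 libraries, and thymic OTII replicate 3 had Hspa1b, a heat shock chaperone, at 113 CPM.

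**Figure D2:**
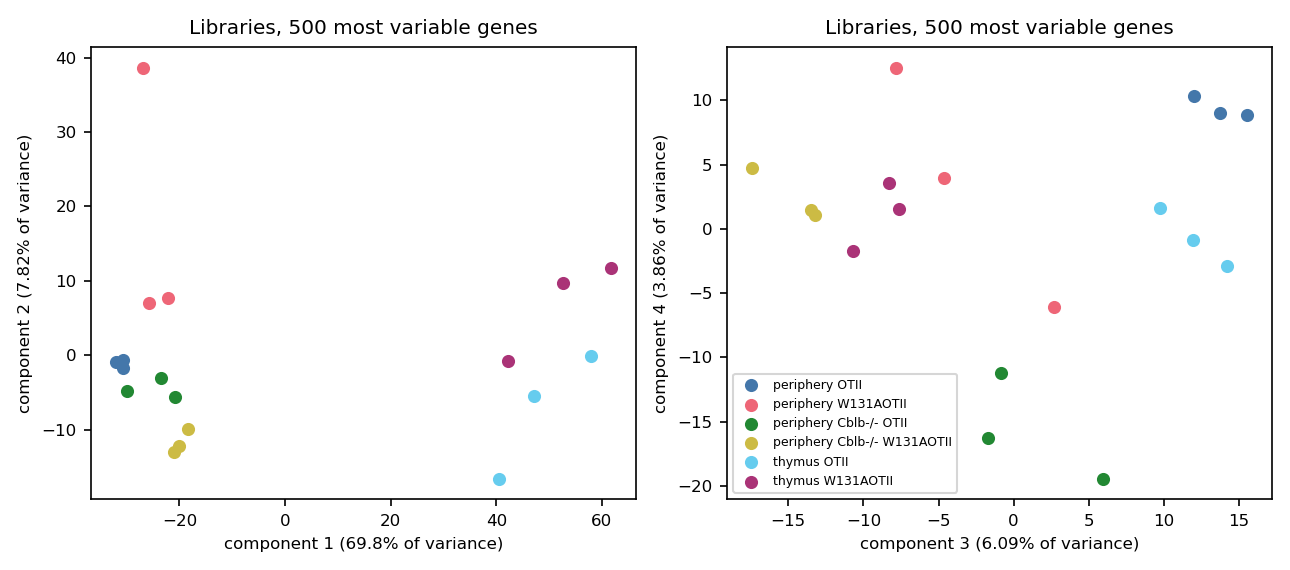
Scores of the 18 libraries on principal components 1 to 4 of log2 CPM (prior count 2) over the 500 most variable genes; each point is a library, coloured by group. Component 1 (69.8% of the variance) parts thymus from periphery, and W131AOTII replicate 2 lies at 38.7 on component 2.

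In peripheral W131AOTII against OTII cells, the comparison that asks what the ZAP-70 substitution changed, genes of regulatory and anergic T cells rose. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), the lineage factor of regulatory T cells, was at 149 ± 11.6 CPM (SD, n = 3) against 31.3 ± 2.90 CPM (log2 fold change 2.25, SE 0.20, edgeR quasi-likelihood adjusted p = 2.1e-06). Lrrc32 (ENSMUSG00000090958, chromosome 7, 98489283 to 98502181), the surface anchor of latent TGF-beta, was at 71.9 ± 8.52 against 11.8 ± 1.65 CPM (log2 fold change 2.61, SE 0.20). Nt5e, the ectonucleotidase CD73, rose by 2.58 (SE 0.30) and Il2ra, the CD25 chain on whose absence the cells were sorted, by 1.57 (SE 0.16). Nrp1 rose by 1.29 (SE 0.15), Ctla4 by 1.80 (SE 0.24), Gpr83 by 1.62 (SE 0.13), Tnfrsf4 by 2.13 (SE 0.24) and Tnfrsf9 by 1.67 (SE 0.20). Of 18 measured regulatory T cell markers, 12 rose, and 18 rose adjusted over the list alone; the list's adjusted p was 0.000216 with an estimated correlation. Of 23 anergy-associated genes 6 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.0155 with an estimated correlation). Both lists hold Izumo1r, Nt5e, Tigit, Ctla4 and Nrp1, so their results are not separate evidence.

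**Figure D3:**
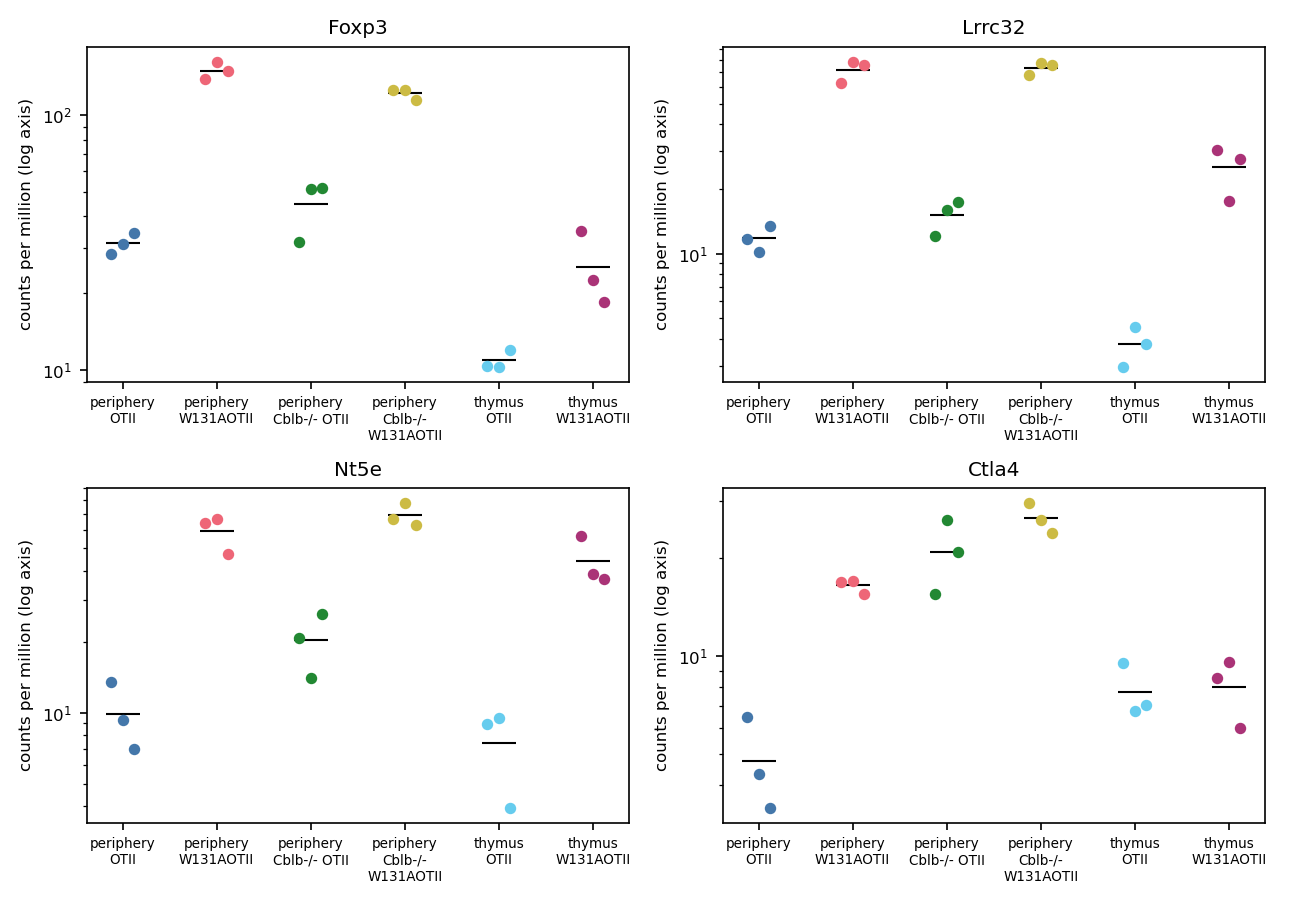
Foxp3, Lrrc32, Nt5e and Ctla4 in CPM (log axis) in the 6 groups; points are libraries and horizontal lines are group means (n = 3). Foxp3 means were 149 and 121 CPM in the peripheral groups with W131A against 31.3 and 44.9 CPM in those without.

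Among the other genes higher in W131AOTII cells were Rgs1, a regulator of G protein signalling (log2 fold change 2.02, SE 0.20), Cish, an inducible cytokine signalling inhibitor (1.35, SE 0.14), Wdfy1 (2.30, SE 0.19), Tspan9 (3.00, SE 0.31), Adam19 (2.06, SE 0.22), Il2rb (2.28, SE 0.25), Bhlhe40 (2.20, SE 0.26) and the chemokine receptor Cxcr3 (2.49, SE 0.29). The genes that fell included Car2 (ENSMUSG00000027562, chromosome 3, 14886273 to 14900770), a carbonic anhydrase, at 10.6 against 43.0 CPM (log2 fold change -2.02, SE 0.18, edgeR adjusted p = 1.4e-06). Rell1 (-1.93, SE 0.20), Jup, which encodes plakoglobin (-1.56, SE 0.22), and Rfwd3 (-1.23, SE 0.17) fell too. Of 25 T cell receptor activity reporters 7 rose and 13 rose adjusted over the list alone (adjusted p = 0.0179 with an estimated correlation), with 4 higher without OTII replicate 2. The 7 were Cd83, Irf4, Nr4a1, Il2ra, Tnfrsf9, Tnfrsf4 and Bhlhe40, and Il2ra and Tnfrsf4 are also on the regulatory T cell list. Egr1 (-0.09), Egr3 (0.54) and Cd69 (0.43) were among those that did not pass. Nr4a1, an immediate product of receptor signalling, rose by 0.65 (SE 0.15, adjusted p = 0.029), which was up to 0.114 without any 1 of OTII replicates 1, 2 and 3 or W131AOTII replicates 1 and 2. Cd5, whose level tracks receptor signal strength, had a log2 fold change of 0.32 (adjusted p = 0.6) and Egr2 0.45 (adjusted p = 0.21), or 0.52 (adjusted p = 0.0296) with voom weights. Of 29 effector and memory genes 8 rose (16 adjusted over the list alone; adjusted p = 0.0179 with an estimated correlation), and 3, 4, 4, 4 and 13 rose without OTII replicates 1, 2 and 3 and W131AOTII replicates 2 and 3. Of 15 NK and innate-like markers, 4 rose, among them Trdc, the constant gene of the delta receptor chain (1.69, SE 0.29); 13 rose adjusted over the list alone (adjusted p = 0.0461 with an estimated correlation), and 1 rose without OTII replicate 1 and 2 without OTII replicates 2 and 3 or W131AOTII replicates 1 and 2.

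In all, 293 of 15204 genes changed, 255 higher and 38 lower, and 241 changed at least 2-fold. With offsets for GC content and length 293 were higher and 80 lower. The count was 148, 161 and 170 without OTII replicates 1, 2 and 3 and 195 without W131AOTII replicate 2. Of 17 inhibitory receptors 2 rose (6 adjusted over the list alone; adjusted p = 0.0461 with an estimated correlation). Among 30 cytokines and cytokine receptors 5 rose, including Lif (4.22, SE 0.67), against 10 adjusted over the list alone (adjusted p = 0.00897 with an estimated correlation), with 3 higher without OTII replicate 1 or 2. Of 23 strong-signal thymic selection genes 5 rose (12 adjusted over the list alone; adjusted p = 0.034 with an estimated correlation), with 1 higher without OTII replicate 1, 2 or 3, 2 without W131AOTII replicate 1 and 3 without W131AOTII replicate 2. Of 95 T cell receptor variable segments 16 were higher and 1 lower (21 and 10 adjusted over the list alone; adjusted p = 0.745 with an estimated correlation), such as Trbv2 (log2 fold change 1.77) and Trbv3 (1.82); 10 were higher without OTII replicate 1 or 3. B cell markers had a median log2 fold change of 1.23 and 1 of 18 past the threshold, Cd72 (1.26, SE 0.27), in the comparison that contains W131AOTII replicate 2; the adjusted p of Cd72 was up to 0.0957 without OTII replicate 1 or 3 or W131AOTII replicate 2.

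In Cbl-b-/-W131AOTII against W131AOTII cells, the comparison for what loss of Cbl-b changed in the anergy model, interferon response genes were among those that fell. Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), the antiviral enzyme viperin, was at 11.2 ± 0.699 CPM (SD, n = 3) against 64.5 ± 19.2 CPM (log2 fold change -2.53, SE 0.21, edgeR quasi-likelihood adjusted p = 1.9e-06). Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731) was at 42.0 ± 8.25 against 173 ± 44.1 CPM (log2 fold change -2.04, SE 0.20) and Ifit1 at 135 ± 16.1 against 473 ± 105 CPM. Cmpk2 (-1.62), Ifitm3 (-3.31), Oasl1 (-1.84), Oas3 (-2.12) and Dhx58 (-1.45) also fell. Of 32 measured interferon response genes, 23 fell and 0 rose, with 30 lower adjusted over the list alone; the list's adjusted p was 0.126 with an estimated correlation. Without Cbl-b-/-W131AOTII replicate 1, 15 of the list fell.

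**Figure D4:**
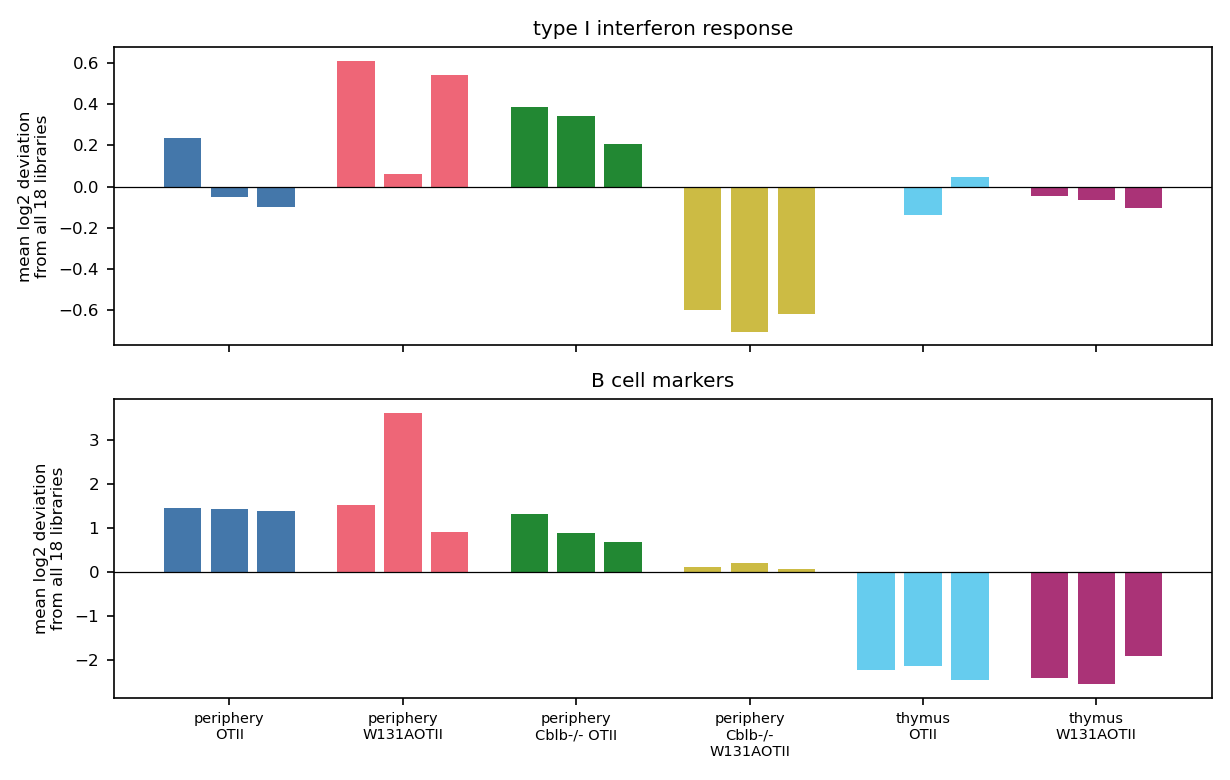
Mean deviation in log2 units from the gene's mean over all libraries, averaged over the type I interferon response list and over the B cell marker list; each bar is 1 of the 18 libraries, grouped by genotype and tissue. The 3 Cbl-b-/-W131AOTII libraries have interferon values of -0.60, -0.71 and -0.62 and the other libraries lie between -0.14 and 0.61.

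Further genes fell in the same comparison. Bcl3, a nuclear partner of NF-kB, fell by 1.29 on the log2 scale (SE 0.18, edgeR adjusted p = 0.00038). Rela (-0.80), the follicular helper factor Bcl6 (-0.94), Ccr4 (-1.11), Il21r (-0.80), the glycolytic enzyme Hk1 (-0.84), Akt2 (-0.69) and Synj2 (-2.32) fell as well. Foxp3, Nt5e and Ctla4, which W131A raised, did not pass in this comparison, with log2 fold changes of -0.29 for Foxp3 (adjusted p = 0.34), 0.22 for Nt5e (adjusted p = 0.65) and 0.69 for Ctla4 (adjusted p = 0.066). Ctla4 passed with DESeq2 (adjusted p = 0.0325), and both Ctla4 (0.00293) and Foxp3 (0.0488) with only the groups compared. Of 18 regulatory T cell markers 2 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.771 with an estimated correlation), with 1 higher without W131AOTII replicate 1 or 2 or Cbl-b-/-W131AOTII replicate 3, 0 higher without W131AOTII replicate 3, and 0 higher and 0 lower without Cbl-b-/-W131AOTII replicate 1. Ikzf2, the Helios factor, rose by 1.63 (SE 0.35, adjusted p = 0.012), which was up to 0.085 without W131AOTII replicate 2 or 3 or Cbl-b-/-W131AOTII replicate 1. Zap70 fell by 0.68 (SE 0.21, adjusted p = 0.043); this was up to 0.151 without W131AOTII replicate 2 or 3 or Cbl-b-/-W131AOTII replicate 1, 2 or 3, and 0.0582 with the replicate number as a block. Genes that rose included Hmgb1, a chromatin protein (1.30, SE 0.14, adjusted p = 3.1e-05), Tbc1d23 (1.60, SE 0.20), Rab4a (2.55, SE 0.40), the ferritin chain Ftl1 (1.68, SE 0.26), Rfwd3 (1.09, SE 0.17), the immediate early factor Fosb (3.35, SE 0.59) and the survival factor Bcl2 (0.76, SE 0.19), whose adjusted p was up to 0.144 without W131AOTII replicate 2 or 3 or Cbl-b-/-W131AOTII replicate 1.

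In this comparison 1407 genes changed, 483 higher and 924 lower. With library size in place of TMM factors, which moved the median of all genes to 0.18, the split was 960 higher and 531 lower, and without the 3 libraries that stood apart 331 genes changed, 63 higher and 268 lower. The count was 322 and 430 without W131AOTII replicates 2 and 3, and 125, 556 and 792 without Cbl-b-/-W131AOTII replicates 1, 2 and 3. Fold changes fell with GC content across genes (Spearman -0.40). The median GC content was 43.3% for genes called higher and 53.8% for genes called lower. Offsets for GC content and length gave 1150 changed genes, 369 higher and 781 lower. Of these, 855 were among the 1407, so many calls in this comparison, in either direction, did not hold with the offsets. B cell transcripts, abundant in W131AOTII replicate 2, moved with the group, and 15 of 18 B cell markers fell (18 adjusted over the list alone; adjusted p = 0.674 with an estimated correlation), with 7 lower without that library and 0 without Cbl-b-/-W131AOTII replicate 1. Cd79a had a log2 fold change of -2.92 (SE 0.54), with an edgeR adjusted p of 0.0547 without Cbl-b-/-W131AOTII replicate 1. The mean log2 deviation of the myeloid and dendritic list was -0.02, -0.33 and -0.55 in Cbl-b-/-W131AOTII replicates 1 to 3. In W131AOTII replicates 1 to 3 it was -0.30, 1.91 and 0.25. Of 61 immunoglobulin segments 45 fell (57 adjusted over the list alone; adjusted p = 0.674 with an estimated correlation), against 3 without W131AOTII replicate 2 and 2, 20 and 17 without Cbl-b-/-W131AOTII replicates 1, 2 and 3. Of 20 glycolysis genes 5 fell (9 adjusted over the list alone; adjusted p = 0.674 with an estimated correlation), with 1 lower without W131AOTII replicate 2 or 3 or Cbl-b-/-W131AOTII replicate 1, and 3 lower without Cbl-b-/-W131AOTII replicate 2 or 3. Of 24 NF-kB genes 5 fell (adjusted p = 0.674 with an estimated correlation), with 3 lower without W131AOTII replicate 2 or 3 or Cbl-b-/-W131AOTII replicate 2 and 2 without Cbl-b-/-W131AOTII replicate 1.

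In Cbl-b-/- OTII against OTII cells, the comparison for Cbl-b loss without W131A, the genes that rose included Igtp and Cxcr3. A processing day or mouse colony shared by the 6 Cbl-b-/- libraries cannot be told apart from loss of Cbl-b in any comparison with the other groups. Igtp, an interferon-inducible GTPase, was at 1510 ± 60.1 CPM (SD, n = 3) against 663 ± 31.8 CPM (log2 fold change 1.19, SE 0.11, edgeR quasi-likelihood adjusted p = 1.1e-05), and Gbp3, a guanylate-binding protein, rose by 1.26 (SE 0.13). The chemokine receptor Cxcr3 was at 20.7 ± 2.02 against 2.53 ± 0.450 CPM (log2 fold change 3.03, SE 0.29). Granzyme B (Gzmb) rose by 4.12 (SE 0.60), S100a4 by 4.70 (SE 0.62), S100a6 by 3.83 (SE 0.56) and Ly6a by 0.98 (SE 0.15). Klrg1, a receptor of terminal effectors, had 573 counts against 1. Ctla4 rose by 2.14 (SE 0.25), Tigit by 2.62 (SE 0.44), Tnfrsf9 by 1.64 (SE 0.20), Tnfrsf4 by 1.97 (SE 0.23) and Penk by 3.09 (SE 0.36).

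The genes lower in Cbl-b-/- OTII cells included Dtx1, a Notch pathway ubiquitin ligase, at 158 ± 12.7 against 538 ± 103 CPM (log2 fold change -1.76, SE 0.22, edgeR adjusted p = 9.4e-05). Trim2 (-2.31), Bpifa2 (-4.65), Aldh1l1 (-2.04) and Unc5a (-1.94) fell too. The immediate early factor Egr1 fell by 1.29 (SE 0.17), and Foxo1, a factor of naive T cells, was at a log2 fold change of -0.63 (adjusted p = 0.014), which was up to 0.1 without OTII replicate 2 or 3 or Cbl-b-/- OTII replicate 2. Foxp3 was at 0.52 (SE 0.20, adjusted p = 0.1). Its adjusted p was 0.0367 without Cbl-b-/- OTII replicate 1 and 0.0174 with offsets for GC content and length. Of 29 effector and memory genes 12 rose (21 higher and 1 lower adjusted over the list alone; adjusted p = 0.158 with an estimated correlation), with 6, 6 and 7 higher without OTII replicates 1 and 3 and Cbl-b-/- OTII replicate 2. Of 15 NK and innate-like markers 3 rose (6 adjusted over the list alone; adjusted p = 0.442 with an estimated correlation), with 1 higher without OTII replicate 2 or 3 or Cbl-b-/- OTII replicate 2. Of 24 tissue handling and heat shock genes 4 rose (6 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation), with 1 higher without OTII replicate 1, 2 or 3 or Cbl-b-/- OTII replicate 1 or 2. Of 17 inhibitory receptors 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.492 with an estimated correlation), with 3 higher without OTII replicate 1 and 2 without OTII replicate 2 or 3 or Cbl-b-/- OTII replicate 2. Of 18 regulatory T cell markers 8 rose (13 adjusted over the list alone; adjusted p = 0.158 with an estimated correlation), with 5, 4 and 4 without OTII replicates 1, 2 and 3. Of 32 interferon response genes 9 rose (10 higher and 1 lower adjusted over the list alone; adjusted p = 0.583 with an estimated correlation), with 3 and 2 without OTII replicates 2 and 3 and 5 and 3 without Cbl-b-/- OTII replicates 1 and 2.

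Here 1249 genes changed, 794 higher and 455 lower, against 349 without the 3 libraries that stood apart and 609 with offsets for GC content and length. The count was 684, 395 and 175 without OTII replicates 1, 2 and 3 and 432 without Cbl-b-/- OTII replicate 2. The balance of directions depended on the libraries, with 324 higher and 360 lower without OTII replicate 1 and 231 higher and 201 lower without Cbl-b-/- OTII replicate 2. With only the groups compared 546 were higher and 480 lower. Calls of ribosomal protein genes depended on single libraries, on OTII replicates 1 to 3 as well as on Cbl-b-/- OTII replicate 2. Of 92, 41 rose and 1 fell (64 and 2 adjusted over the list alone; adjusted p = 0.442 with an estimated correlation), against 2 higher without it and 4, 15 and 2 without OTII replicates 1, 2 and 3. Of 30 cell cycle genes 7 rose (14 adjusted over the list alone; adjusted p = 0.8 with an estimated correlation), including Ccnb2 (3.65, SE 0.61), with 3, 4 and 2 without OTII replicates 1, 2 and 3 and 3 without Cbl-b-/- OTII replicate 2. The mitochondrial gene mt-Nd3 (ENSMUSG00000064360, chromosome M, 9459 to 9806) had 0 counts in the Cbl-b-/- OTII libraries against 45 in OTII, at least 12.3-fold lower against a floor of 3 counts over the group. It also had 0 counts in Cbl-b-/-W131AOTII libraries against 60 in W131AOTII, at least 18.3-fold lower.

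In Cbl-b-/-W131AOTII against Cbl-b-/- OTII cells, which asks what W131A changed where Cbl-b was lacking, the genes that rose again included Lrrc32 (log2 fold change 2.28, SE 0.20, edgeR quasi-likelihood adjusted p = 4.5e-06), Foxp3 (1.43, SE 0.20, adjusted p = 0.00028), Wdfy1 (1.95, SE 0.19), Gpr83 (1.17, SE 0.13), Nrp1 (1.32, SE 0.15), Il2ra (1.25, SE 0.16), Cish (1.09, SE 0.14), Nt5e (1.76, SE 0.29) and Bcl2 (1.10, SE 0.19). Foxp3 was at 121 ± 6.18 against 44.9 ± 11.4 CPM (SD, n = 3). Car2 (-1.95, SE 0.17), Rell1 (-1.85) and Jup (-1.82) fell. Igtp was at 695 ± 65.0 against 1510 ± 60.1 CPM and fell by 1.12, and Irgm1, another interferon-inducible GTPase, fell by 1.05. Ifit3 (-1.71, SE 0.20), Rsad2 (-1.68), Oasl2 (-1.54) and Ly6a (-1.16) fell. Of 32 interferon response genes 23 fell (29 adjusted over the list alone; adjusted p = 0.0366 with an estimated correlation). Of 18 regulatory T cell markers 8 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.0783 with an estimated correlation). Ctla4 was at 0.35 (adjusted p = 0.47), or 0.68 (adjusted p = 0.00275) with voom weights.

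A total of 287 genes changed, 122 higher and 165 lower, or 186 and 116 with library size in place of TMM factors. The count was 176 and 1047 without Cbl-b-/- OTII replicates 1 and 3, and 171, 146 and 153 without Cbl-b-/-W131AOTII replicates 1, 2 and 3. Of 25 T cell receptor activity reporters 3 rose (8 adjusted over the list alone; adjusted p = 0.275 with an estimated correlation), with 5 higher without Cbl-b-/- OTII replicate 3. The myeloid marker Mpeg1 fell by 3.50 (SE 0.67); of 16 myeloid and dendritic cell markers 3 fell (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.655 with an estimated correlation), with 5 lower without Cbl-b-/- OTII replicate 3 and 1 without Cbl-b-/- OTII replicate 2 or Cbl-b-/-W131AOTII replicate 1, 2 or 3. B cell markers had a median of -0.87, with 1 of 18 higher (1 higher and 4 lower adjusted over the list alone; adjusted p = 0.655 with an estimated correlation) and 0 higher without Cbl-b-/- OTII replicate 2 or Cbl-b-/-W131AOTII replicate 2 or 3. Ribosomal protein genes had a median of -0.54, or -0.18 without Cbl-b-/- OTII replicate 2. Of 92, 2 fell (40 adjusted over the list alone; adjusted p = 0.655 with an estimated correlation), with 44 lower without Cbl-b-/- OTII replicate 3 and 0 without Cbl-b-/- OTII replicate 1 or 2 or Cbl-b-/-W131AOTII replicate 1, 2 or 3.

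In Cbl-b-/-W131AOTII against OTII cells, where both changes were present, Rgs1 rose by 2.74 (SE 0.20, edgeR quasi-likelihood adjusted p = 3.8e-07), Lrrc32 by 2.64 (SE 0.21), Foxp3 by 1.96 (SE 0.20), Ikzf2 by 3.22 (SE 0.38), Ctla4 by 2.49 (SE 0.25), Nt5e by 2.80 (SE 0.30), Tnfrsf9 by 2.19 (SE 0.20), Il2ra by 1.77 (SE 0.16) and Bcl2 by 1.31 (SE 0.19). Rsad2 (-2.13, SE 0.21), Ifit1 (-1.44, SE 0.18), Oasl1 (-1.45), Synj2 (-2.32), Car2 (-1.40), Jup (-2.28) and Epb41l1 (-2.57) fell. Cblb was at -0.47 (SE 0.17, adjusted p = 0.1). Its adjusted p was 0.0169 with offsets for GC content and length and 0.00648 with only the groups compared. Of 18 regulatory T cell markers 14 rose (16 adjusted over the list alone; adjusted p = 0.00576 with an estimated correlation). Of 32 interferon response genes 13 fell (20 lower and 1 higher adjusted over the list alone; adjusted p = 0.308 with an estimated correlation). Of 17 inhibitory receptors 6 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.338 with an estimated correlation). Of 18 B cell markers 3 fell (12 adjusted over the list alone; adjusted p = 0.419 with an estimated correlation), with 0 lower without any 1 of OTII or Cbl-b-/-W131AOTII replicates 1, 2 and 3. Cd79a was at 8.82 against 30.2 CPM. Of 95 T cell receptor variable segments 15 rose and 13 fell (17 and 16 adjusted over the list alone; adjusted p = 0.662 with an estimated correlation). Without OTII replicates 2 and 3, 2 and 3 of these fell, and without Cbl-b-/-W131AOTII replicates 1, 2 and 3, 2, 6 and 8 fell. Here 1123 genes changed, 588 higher and 535 lower, or 833 and 339 with library size in place of TMM factors (median 0.16) and 481 and 858 with offsets for GC content and length. The count was 396 and 368 without OTII replicates 2 and 3 and 390 and 573 without Cbl-b-/-W131AOTII replicates 1 and 2.

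The interaction tested whether the W131A effect differed between cells with and without Cbl-b. Most genes past the threshold had a lower W131A effect where Cbl-b was lacking. The difference was -3.53 (SE 0.39, edgeR quasi-likelihood adjusted p = 0.0002) for Cxcr3, -2.89 (SE 0.33) for the ISG15-conjugating enzyme Ube2l6, -2.25 (SE 0.26) for Oasl2, -2.24 (SE 0.28) for Ifit3, -2.07 (SE 0.28) for Rsad2, -3.26 (SE 0.41) for Ifitm3, -1.70 (SE 0.21) for Ly6a and -7.03 (SE 0.83) for Il1rl1, the IL-33 receptor. Rfwd3 (1.48, SE 0.24) and Trim2 (1.98, SE 0.35) differed the other way. Of 32 interferon response genes 19 were lower (28 adjusted over the list alone; adjusted p = 0.0138 with an estimated correlation). For Foxp3 the difference was -0.82 (SE 0.28, adjusted p = 0.25) and for Ctla4 -1.45 (SE 0.33, adjusted p = 0.053). The Ctla4 difference lay next to the threshold. It passed with DESeq2 (adjusted p = 0.00216), with the replicate number as a block (0.0403), without OTII replicate 1 (0.0185) and without Cbl-b-/- OTII replicate 1 (0.0299). Of 29 effector genes 5 were lower (14 adjusted over the list alone; adjusted p = 0.0778 with an estimated correlation), with 2 without OTII replicate 1 or 3 and 3 without Cbl-b-/-W131AOTII replicate 1 or 2. There were 96 genes past the threshold, 6 higher and 90 lower, against 60 without OTII replicate 1 and 219 without Cbl-b-/- OTII replicate 3.

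Across the tested genes, which are not independent replicates, the W131A effects with and without Cbl-b had a Pearson r of 0.06. Spearman rho was -0.03, and the jackknife SE over libraries was 0.122 for r. This SE and those of r below treat all libraries as 1 sample and not as fixed groups, so they are a rough guide to the spread. In simulated data r over all genes was 0.0745 with the same effects in both backgrounds and 0.0173 with effects in 1. An r of 0.06 over all genes therefore does not show that the effects differ. Over the genes called in W131AOTII against OTII cells r was 0.48. Of 88 genes called in both, 82 moved in the same direction, 65 higher and 17 lower. It was 55 of 57 without Cbl-b-/-W131AOTII replicate 2. Lrrc32, Foxp3, Car2 and Rell1 were among the 82. Were every gene equally likely to be called, 2.05 higher and 0.412 lower in both would be met. Both comparisons come from 1 fit that shares its spread per gene, so genes are not equally likely to be called. An excess over such numbers is therefore no test, here and below. The Cbl-b effects with and without W131A had an r of 0.21 (rho 0.33, SE 0.0977). Of genes called in both, 284 of 295 moved in the same direction, 106 higher and 178 lower, against 25.2 and 27.7 were all genes equally likely. These became 102 of 105 and 52 of 55 without OTII replicates 2 and 3, 91 of 97 and 90 of 97 without W131AOTII replicates 2 and 3. They became 152 of 159 and 174 of 179 without Cbl-b-/- OTII replicates 1 and 2, and 37 of 40 and 130 of 133 without Cbl-b-/-W131AOTII replicates 1 and 2. With offsets for GC content and length they were 116 of 127, and without the 3 libraries that stood apart 45 of 50.

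In thymic W131AOTII against OTII cells, which asks what the substitution changed in thymocytes, Lrrc32 (log2 fold change 2.73, SE 0.22, edgeR quasi-likelihood adjusted p = 1.4e-06), Nt5e (2.56, SE 0.30), Il2ra (1.36, SE 0.16), Foxp3 (1.22, SE 0.20), Cish (0.98, SE 0.14) and the cytokine signalling inhibitor Socs3 (1.41, SE 0.15) rose. Foxp3 was at 25.3 ± 8.61 against 10.9 ± 0.951 CPM (SD, n = 3). Eomes, a factor of cytotoxic and memory T cells, rose by 3.7 (SE 0.34), Tspan9 by 3.60 (SE 0.31), the perforin gene Prf1 by 1.57 (SE 0.20), Cxcr3 by 2.00 (SE 0.27) and Zbtb16, the PLZF factor of innate-like T cells, by 3.85 (SE 0.53). Ppp3cc, a catalytic subunit of calcineurin, was at 169 ± 42.2 against 53.3 CPM (log2 fold change 1.67, SE 0.15). Receptor signal reporters moved both ways, and Cd5 and Nr4a1 were among those that fell. Cd5 (ENSMUSG00000024669, chromosome 19, 10717116 to 10739002) was at 192 ± 48.5 against 490 ± 22.1 CPM (log2 fold change -1.35, SE 0.16, adjusted p = 5.9e-05), and Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795) at 124 ± 26.4 against 241 ± 14.1 CPM (-0.96, SE 0.15). Cd6 (-0.89), Ndrg1, a factor linked to anergy (-1.55), Klf2, which controls exit from the thymus (-1.11), and Car2 (-1.18) fell. Egr2 was at -0.66 (SE 0.15, adjusted p = 0.02), which was up to 0.106 without thymic OTII replicate 1 or 3 or W131AOTII replicate 2.

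Of 25 T cell receptor activity reporters in the thymus 4 rose and 6 fell (5 and 10 adjusted over the list alone; adjusted p = 0.666 with an estimated correlation); 2 rose without OTII replicate 1 or W131AOTII replicate 1 or 3 and 1 without OTII replicate 3. Of 18 regulatory T cell markers 4 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.466 with an estimated correlation). Of 29 effector genes 6 rose (10 higher and 1 lower adjusted over the list alone; adjusted p = 0.466 with an estimated correlation), with 2 without OTII replicate 1 or 3. Among erythroid transcripts Hba-a1, a haemoglobin chain, had 0 counts in OTII and 103 in W131AOTII thymocytes. That was at least 29.95-fold higher against 3 counts over the group. Hba-a1 was at 0.77, 0.34 and 2.88 CPM in W131AOTII replicates 1 to 3. Its call was lost without OTII replicate 3 or W131AOTII replicate 3 (edgeR adjusted p up to 0.059). In all, 421 genes changed, 263 higher and 158 lower, or 294 and 298 with offsets for GC content and length, and 278 without the 3 libraries that stood apart. The count was 248 and 176 without thymic OTII replicates 1 and 3 and 208 without thymic W131AOTII replicate 3. A split of the thymic libraries that mixed the genotypes gave 159 genes.

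The W131A effect differed between the periphery and the thymus for receptor signal genes, among others. The difference was 1.61 (SE 0.22, edgeR quasi-likelihood adjusted p = 0.00087) for Nr4a1 and 1.67 (SE 0.23, adjusted p = 0.00096) for Cd5, which fell in the thymus, and 2.36 (SE 0.31) for Irf4, 2.33 (SE 0.18) for Gpr83, 2.46 (SE 0.32) for Tnfrsf4, 2.79 (SE 0.37) for Gadd45g and 1.34 (SE 0.22) for Klf2. Ppp3cc (-1.31, SE 0.21) and Sqor (-1.44, SE 0.22) differed the other way. For Foxp3 the difference was 1.03 (SE 0.28, adjusted p = 0.15) and for Nt5e 0.02 (SE 0.41). For Foxp3 the adjusted p was 0.0106 without thymic W131AOTII replicate 1 and 0.04 with DESeq2. Of 25 T cell receptor activity reporters 6 were higher (11 adjusted over the list alone; adjusted p = 0.0237 with an estimated correlation). Across genes the W131A effects in the 2 tissues had an r of 0.30 (rho 0.17, jackknife SE 0.139). Of genes called in both, 84 of 91 moved in the same direction, or 58 of 60 without peripheral OTII replicate 1. The 84 were 71 higher and 13 lower, against 4.41 and 0.395 were all genes equally likely to be called. There were 58 genes past the threshold, 45 higher and 13 lower, or 34 and 4 without the 3 libraries that stood apart. The count was 37 and 24 without peripheral OTII replicates 2 and 3, 32 and 29 without peripheral W131AOTII replicates 1 and 2, and 117 and 36 without thymic W131AOTII replicates 1 and 3.

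**Figure D5:**
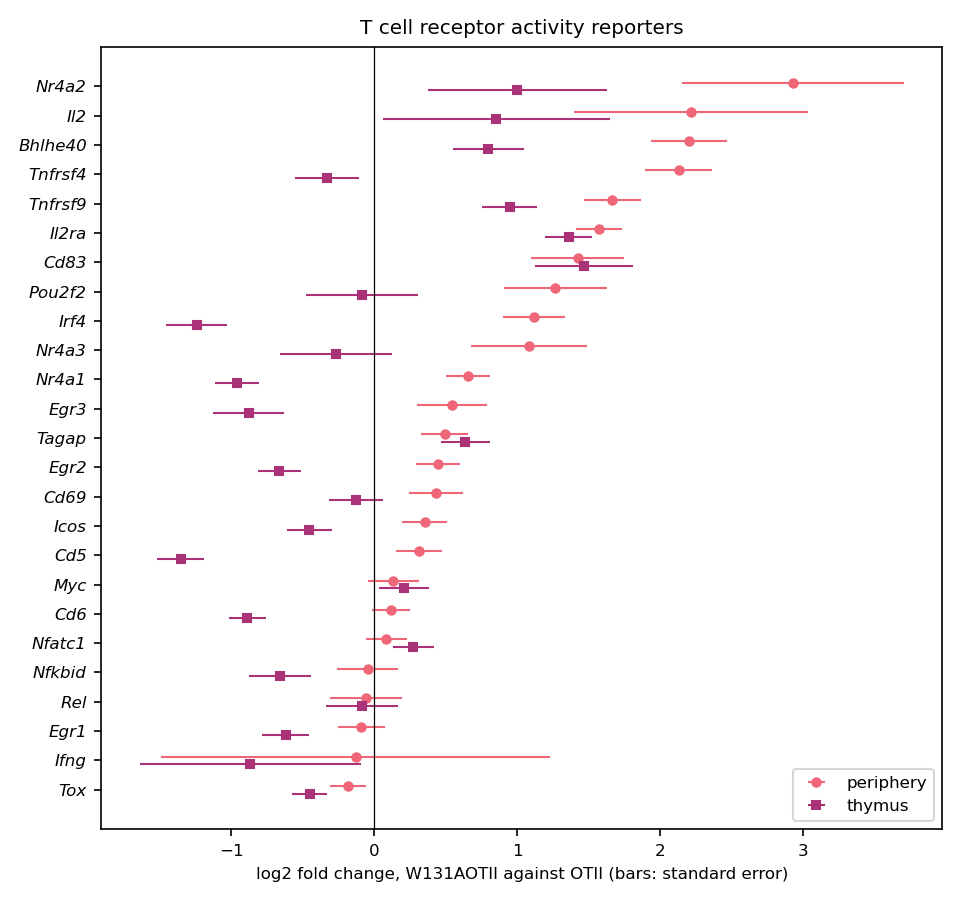
Log2 fold change of W131AOTII against OTII for the 25 T cell receptor activity reporters in the periphery and in the thymus. Circles (periphery) and squares (thymus) are fitted values, and error bars are the SE (3 libraries per group). Cd5 is at 0.32 in the periphery and -1.35 in the thymus, and Nr4a1 at 0.65 and -0.96.

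In peripheral against thymic OTII cells, the tissue reference for the effects above, Ccr4 was at 4.55 against 86.7 CPM (log2 fold change -4.25, SE 0.22, edgeR quasi-likelihood adjusted p = 2.7e-10). Ccr9, a thymic homing receptor, was at a log2 fold change of -3.18 (SE 0.25), Egr2 at -2.66 (SE 0.16), Nr4a1 at -2.60 (SE 0.16), Pdcd1 at -4.21 (SE 0.35), Itm2a at -2.68 (SE 0.20) and Tox at -1.52 (SE 0.13). Cell cycle genes Tpx2 (-5.27, SE 0.46) and Top2a (-4.09, SE 0.38) were lower too. Genes higher in the periphery included Ly6c1 at 659 against 92.3 CPM (2.84, SE 0.15), Socs3 (2.92, SE 0.16), Prf1 (2.99, SE 0.21), Dapl1 (3.03, SE 0.31), Foxp3 (1.52, SE 0.20) and S1pr1, the receptor for exit into lymph (0.89, SE 0.12). The B cell gene Ms4a1 was at 5.89 (SE 0.71) and Ighm at 1.5 (SE 0.15). A total of 2785 genes changed, 1179 higher and 1606 lower, or 2546 and 1624 with offsets for GC content and length.

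By list, the periphery was lower for 18 and higher for 1 of 24 immature thymocyte genes (18 and 2 adjusted over the list alone; adjusted p = 0.00865 with an estimated correlation), lower for 23 of 30 cell cycle genes (25; 0.308) and lower for 15 and higher for 4 of 25 T cell receptor activity reporters (15 and 4; 0.156), where the paired values are the count adjusted over the list alone and the adjusted p with an estimated correlation. It was lower for 12 and higher for 1 of 23 strong-signal thymic selection genes (15 and 1; 0.0569), with 0 higher without peripheral OTII replicate 1 or thymic OTII replicate 2. It was lower for 9 and higher for 5 of 16 follicular helper genes, with Icos at -2.17, and 3 were higher without OTII replicate 1, 2 or 3 of the periphery (10 and 5; 0.177). Naive and quiescence genes were higher for 7 and lower for 4 of 23 (8 and 4; 0.495), with 2 lower without peripheral OTII replicates 1 or 2 or thymic OTII replicates 1 or 3. Negative regulators of T cell receptor signalling were lower for 12 and higher for 4 of 35 (14 and 5; 0.427). Proximal T cell receptor signalling genes were higher for 4, such as the kinase Tec at 1.70, and lower for 3 of 28 (4 and 4; 0.754), calcium and NFAT genes higher for 3 and lower for 2 of 22 (3 and 2; 0.537) and PI3K, AKT and mTOR genes higher for 3 of 26, such as Pik3cb at 1.0 (3; 0.43). Apoptosis and survival genes were higher for 4 and lower for 4 of 27 (4 and 4; 0.742), with Bcl2l1 at -0.98 and 2 lower without peripheral OTII replicate 1. Cholesterol synthesis genes were higher for 5 and lower for 1 of 24 (6 and 2; 0.427). Unfolded protein response genes were lower for 5 and higher for 1 of 19 (6 and 1; 0.537), with Atf6 at -1.57; 3 were lower without peripheral OTII replicate 1 or thymic OTII replicate 3 and 2 without peripheral OTII replicate 3 or thymic OTII replicate 2. Tissue handling and heat shock genes were lower for 4 and higher for 1 of 24 (4 and 1; 0.742), with Fos at -2.50 and 2 lower without peripheral OTII replicate 1 or thymic OTII replicate 3.

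Among lists of other cells and controls, B cell markers were higher in the periphery for 17 of 18 (18 adjusted over the list alone; adjusted p = 0.308 with an estimated correlation), immunoglobulin segments for 46 of 61 (56; 0.427) and myeloid and dendritic cell markers for 4 of 16 (4; 0.742), with 2 of the latter without peripheral OTII replicate 2 or 3 or thymic OTII replicate 2. CD8 T cell markers were lower for 3 and higher for 1 of 8 (3 and 2; 0.709), with Cd8a at -1.76, and thymic stroma and epithelium markers lower for 2 of 5 (3; 0.427). Histone genes were lower for 5 and higher for 2 of 25 (5 and 4; 0.893), T cell receptor variable segments lower for 12 of 95 (11; 0.427) and the housekeeping gene Sdha higher by 0.57, as 1 of 14 (1; 0.709). The erythroid and platelet, sex-linked and mitochondrially encoded lists had median log2 fold changes of -0.15, -0.14 and 0.11 there, with adjusted p of 0.893, 0.89 and 0.89 with an estimated correlation.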

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

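The tests of explanations and the counts over other splits of the libraries below were all chosen after the results were seen, while the comparisons, the gene lists and the edgeR tests were fixed earlier.

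The W131A effect differed between cells with and without Cbl-b, by a test of the difference itself, for 96 genes and for the type I interferon response list (adjusted p = 0.0138 with an estimated correlation). The differences, as log2 values, were -3.53 for Cxcr3, -2.89 for Ube2l6, -2.25 for Oasl2, -2.44 for Ifit3b, -7.03 for Il1rl1, -2.24 for Ifit3, -1.66 for Cmpk2, -1.70 for Ly6a, -3.26 for Ifitm3, -2.88 for Ccrl2 and -2.07 for Rsad2. Rfwd3 (1.48), Trim2 (1.98) and Hmgb1 (1.04) differed the other way, and the adjusted p of Hmgb1 was up to 0.0563 without OTII replicate 3 or W131AOTII replicate 2. Of all 200 splits of the libraries within the 2 backgrounds, 2 gave as many genes as the real 96, a share of 0.01. The other split with as many genes, at 502, exchanged the genotype labels in 1 background. That exchange turns the difference into the W131A effect shared by both, a structure of the samples. The next highest split gave 75 genes. Splits that mix genotypes within a background also break up the W131A effect itself. The share therefore cannot decide whether the difference between the effects arose by chance.

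The W131A effect also differed between periphery and thymus, by a test of the difference itself, for 58 genes. Estimated-correlation adjusted p for lists of the difference was 0.0237 for anergy-associated genes, 0.0237 for T cell receptor activity reporters, 0.0351 for inhibitory receptors, 0.0207 for regulatory T cell markers and 0.0207 for strong-signal thymic selection genes. The differences, as log2 values, were 2.33 for Gpr83, 3.37 for Ncmap, 2.36 for Irf4, 2.89 for Ccr8, 1.87 for Nacc2, 2.46 for Tnfrsf4, 2.79 for Gadd45g, 1.17 for Samhd1, 1.61 for Nr4a1 and 1.67 for Cd5. They were -1.44 for Sqor, -1.63 for Slc16a5, -1.48 for Tmie and -1.31 for Ppp3cc. Calls that single libraries decided were Cd6 (1.0; adjusted p = 0.0577 without thymic W131AOTII replicate 3), Nrp1 (1.11; 0.0663 without peripheral OTII replicate 3), and Adamts14 (-1.33; up to 0.0739) and Wnt5b (-1.62; up to 0.063), both without peripheral OTII replicate 3 or W131AOTII replicate 1 or 2. Of 200 splits, 11 gave as many genes as the real 58, a share of 0.055, with a highest other count of 622, so chance was not excluded. All 10 of the other splits with as many genes kept the real grouping of at least 1 tissue. The split at 622 kept the peripheral genotypes and mixed those of the thymus. It set thymic OTII replicates 1 and 3 and W131AOTII replicate 2 against the other thymic libraries. The split at 620 exchanged the genotype labels in 1 tissue. Counts of that size point to structures of the samples, of which 1 cut across genotype in the thymus.

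Further genes of that difference were Abhd15 (-1.07), Art2b (-1.28), Tgm1 (adjusted p = 0.0429), Gprin3 (-1.66), Ctla4 (1.75), Egr2 (1.11) and Ikzf4 (1.21). Each of these but Ikzf4 lost its call on the removal of single libraries. Numbering peripheral OTII as PO, peripheral W131AOTII as PW, thymic OTII as TO and thymic W131AOTII as TW, the adjusted p was up to 0.115 for Abhd15 without replicate 2 or 3 of PO, 1 or 2 of PW, 1 or 3 of TO or 2 or 3 of TW, and up to 0.134 for Art2b without any of PO or TO, 1 or 2 of PW or 3 of TW. It was up to 0.0999 for Tgm1 without any of PO or TO, 1 or 2 of PW or 2 or 3 of TW, and up to 0.123 for Gprin3 without any of PO, 2 or 3 of PW, 1 or 3 of TO or 2 or 3 of TW. For Ctla4 it was up to 0.0899 without 2 or 3 of PO, 1 or 2 of PW, 1 of TO or 3 of TW, and for Egr2 up to 0.0901 without 3 of PO, 1 or 2 of PW, 1 or 3 of TO or 2 of TW.

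The other comparisons had 10 splits each, whose share is never under 0.1. The real split was the 1 that gave as many genes, at 293 for W131AOTII against OTII (highest other 0), 1407 for Cbl-b-/-W131AOTII against W131AOTII (highest other 1), 1249 for Cbl-b-/- OTII against OTII (highest other 0) and 287 for Cbl-b-/-W131AOTII against Cbl-b-/- OTII (highest other 0). It was also the 1 such split at 1123 for Cbl-b-/-W131AOTII against OTII (highest other 0), 421 for thymic W131AOTII against OTII (highest other 159) and 2785 for peripheral against thymic OTII (highest other 0). The thymic split at 159 mixed the genotypes, with OTII replicates 1 and 3 and W131AOTII replicate 2 on 1 side. Those libraries were at 47.1, 40.6 and 42.1 on component 1 of the 500 most variable genes. Thymic OTII replicate 2 and W131AOTII replicates 1 and 3 were at 57.8, 61.75 and 52.5. The thymic libraries thus also differed across genotypes, and the cause was not tested.

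In the first pattern weighed, interferon response genes were lower in Cbl-b-/-W131AOTII than in W131AOTII cells, with 23 of 32 members lower. The list's adjusted p was 0.126 with an estimated correlation, and 15 members were lower without Cbl-b-/-W131AOTII replicate 1. Without W131AOTII replicate 2, which carried B cell and myeloid transcripts, 21 of the 23 members were lower too. That library had the lowest interferon list value of its group (0.06 against 0.61 and 0.54), so the fall did not rest on it. B cell list values were 0.12, 0.21 and 0.08 in the Cbl-b-/-W131AOTII libraries, below the other 9 peripheral libraries. Whether that bears on the interferon genes was not tested. A trend with GC content and length was not the whole cause. With offsets added, 22 members were lower in both fits and the list's median went from -1.03 to -1.04. An exposure or a processing day shared by the 3 Cbl-b-/-W131AOTII libraries cannot be told apart from the genotype, because 21 members had all 3 of these libraries below the other 9 peripheral libraries and the labels give no day. Hspa1b, which can follow tissue handling, was at 93.2 CPM in the same 3 libraries against 7.42 in W131AOTII and 31.3 in Cbl-b-/- OTII cells. It was also raised in libraries without low interferon list values. These values were 0.39, 0.34 and 0.21 in Cbl-b-/- OTII libraries and 0.05 in thymic OTII replicate 3, where Hspa1b was at 113 CPM. A shared exposure or day stays open. A biological explanation, that loss of Cbl-b together with W131A lowers interferon signalling in resting T cells, may hold and was not tested further.

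In the second pattern, regulatory T cell markers were higher in W131AOTII than in OTII cells. More cells of every other type alike were argued against, since without W131AOTII replicate 2 the median log2 fold change was -0.25 (-0.2507) for B cell markers and -0.02 for myeloid markers against 1.67 for regulatory T cell markers. In the same fit the NK, effector and CD8 T cell lists had medians of 1.31, 1.46 and 0.42, so that more cells of those types stay open, although the sort for CD4, low CD44 and CD62L was set to leave them out. A GC and length trend was argued against, since 12 of the 12 markers stayed higher with offsets (median 1.59). A larger share of Foxp3-expressing cells may have been left in the sort, despite the removal of CD25-positive cells. This cannot be told apart from a change within each cell, since the 12 markers were measured in bulk. The receptor segments counted also differed between the groups. Trbv12-2 made up 29.4% of beta variable counts in W131AOTII against 50.8% in OTII cells, and whether this goes with the markers was not tested. W131A may raise the regulatory T cell markers through receptor signalling, which was not tested.

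In the third pattern, mt-Nd3 and 3 genes near Cblb differed in both Cbl-b-/- comparisons. A mitochondrial sequence variant against the reference is a candidate explanation for mt-Nd3, which had 0 counts in all 6 Cbl-b-/- libraries and 6 to 39 in each of the other 12, while the other 14 mitochondrial genes had median log2 fold changes of 0.41 (0.414) and 0.30. DNA of another strain around the targeted locus stays open. Of 24 tested genes within 5 Mb of Cblb 3 changed alike in both comparisons, against 280 of 15179 elsewhere (one-sided Fisher's exact p = 0.00967), but Cep97, Gm8900 and Gm17809 lie within 57.6 kb of each other on chromosome 16 and may count as 1 place, a condition added after that p was seen. No biological explanation was tested.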

How the results depend on the processing

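Of the alternatives, the offsets for GC content and length and the fit without the 3 libraries that stood apart (W131AOTII replicate 2, Cbl-b-/- OTII replicate 2 and thymic OTII replicate 3) were chosen after the data were seen. No call among the 659 named gene results reversed in the alternatives run for them. The difference of the W131A effect on Nt5e between periphery and thymus, near 0, was -0.115 with voom weights and ran from -0.203 to 0.319 with 1 library left out. Of called genes, 369 of 659 gene results kept their call with every 1 of the libraries left out. Of gene results, 3 of 659 lost their call with RLE factors, 39 with library size alone, 13 without a filter, 2 of 641 with CPM above 1 in at least 3 libraries, 0 of 646 with DESeq2, 20 with voom weights, 2 of 594 with segments, sex-linked, mitochondrial and ribosomal genes left out, 79 of 645 with only the groups compared, 83 with offsets and 157 without the 3 libraries. Where counts moved by more than 1.5 times the cause was not tested. Simulated data recovered 22.4% of genes with a 2-fold difference between effects, against 65.7% and 61.2% of genes that differed 2-fold in 2 comparisons of 2 groups. Depth limits genes under 3 counts over a group to bounds.

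In the order W131AOTII against OTII, Cbl-b-/-W131AOTII against W131AOTII, Cbl-b-/- OTII against OTII, Cbl-b-/-W131AOTII against Cbl-b-/- OTII, Cbl-b-/-W131AOTII against OTII, interaction, thymic W131AOTII against OTII, and W131A effect in periphery against thymus, counts without a low-count filter were 772, 2243, 1907, 1180, 1816, 832, 821 and 365. With DESeq2 they were 478, 2243, 2069, 680, 1735, 234, 789 and 210. With voom weights they were 641, 3517, 5467, 2722, 4696, 694, 2222 and 556, and 4542 for peripheral against thymic OTII. With only the groups compared, counts were 510 for W131AOTII against OTII, 3296 for Cbl-b-/-W131AOTII against W131AOTII, 3878 for Cbl-b-/-W131AOTII against OTII and 140 in the thymus. With offsets they were 609 for Cbl-b-/- OTII against OTII, 583 for Cbl-b-/-W131AOTII against Cbl-b-/- OTII and 102 for periphery against thymus. Without the 3 libraries they were 331 for Cbl-b-/-W131AOTII against W131AOTII, 349 for Cbl-b-/- OTII against OTII, 278 in the thymus and 38 for periphery against thymus. With 1 library left out, counts ran from 148 to 341, 125 to 1405, 175 to 1661, 146 to 1047, 368 to 836, 60 to 219, 176 to 527 and 24 to 117 in the order above, and from 1949 to 2380 for peripheral against thymic OTII.

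The r of the Cbl-b effects was 0.0625 without a filter, 0.325 with only the groups compared and 0.458 over genes above 10 CPM. It ran from 0.145 to 0.254 with 1 library left out. With offsets for GC content and length it was 0.15 (rho 0.21). Fold changes fell with GC content in both Cbl-b comparisons (Spearman -0.40 with W131A and -0.27 without). Between the 2 Cbl-b-/- groups the Spearman value was -0.05. Whether the trend comes from Cbl-b loss or from a day or colony shared by the Cbl-b-/- libraries cannot be told apart. The r of the W131A effects in periphery and thymus was 0.0723 without a filter and ran from 0.18 to 0.363 with 1 library left out, and that with and without Cbl-b from 0.000767 to 0.142. Of 130 list calls over the 9 comparisons, 17 held with an estimated correlation and 56 calls were made with fry, 51 of them the same. Over 2000 genes, component 1 held 53.3%.

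With the replicate number as a block, counts were 262, 1074, 1074, 239, 993, 87, 376, 47 and 2650 in the same order and peripheral against thymic OTII last, so that the block changed no count of calls by more than 1.5 times; 48 of 659 gene calls and 3 of 130 list calls were lost with it. The numbers are not stated to pair libraries. The 45 correlations of libraries with the same number, group means removed, ran from -0.304 to 0.205, 6 above 0.1 and 8 below -0.1, with 0 of 15 group pairs above 0.1 throughout, so the numbers were not taken as pairs.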

Other observations

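The mean share of Trbv12-2 in T cell receptor beta variable counts, which was not tested, was 50.8% ± 2.46 (SD, n = 3) in peripheral OTII, 29.4% ± 4.64 in W131AOTII, 46.0% ± 4.22 in Cbl-b-/- OTII and 32.1% ± 2.90 in Cbl-b-/-W131AOTII cells. In the thymus it was 37.2% ± 4.99 in OTII and 32.2% ± 3.65 in W131AOTII cells, with overlapping ranges. How reads of 50 bases were parted between this segment and the closely related Trbv12-1 is not given in the sources used here, so the share is of counts assigned to Trbv12-2.

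The heat shock chaperone gene Hspa1b was at 0.843 ± 0.24 CPM (SD, n = 3) in OTII, 7.42 ± 10.4 in W131AOTII, 31.3 ± 5.05 in Cbl-b-/- OTII and 93.2 ± 35.4 in Cbl-b-/-W131AOTII cells, and Hspa1a at 0.0673, 1.26, 4.03 and 13.4 CPM in the same order. In thymic OTII libraries Hspa1b was at 37.8 ± 65.1 CPM, with replicate 3 at 113 CPM, and in thymic W131AOTII libraries at 1.18 CPM. Fosb, Hspa1a and Hspa1b can also follow tissue handling, and the labels give no handling times.

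Over the 18 pairs of libraries within a group, chi-square per degree of freedom between the counts ran from 12.5 to 119.5, where repeat sequencing of 1 library would give about 1.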
